A study of Gallus gallus with 12 samples.

How the data were processed

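RNA from the bone marrow of the right tibia was measured on a spotted chicken array in 12 samples, 6 from layer hens and 6 from broiler hens, all 15 weeks old. Per the labels, the marrow was not separated into cell types, and 20 µg of RNA per sample was labelled as cDNA by an indirect method with a dye named for 555 or 647 nm. Each slide carried 1 layer and 1 broiler sample in opposite dyes. Each breed had the 555 dye on 3 slides and the 647 dye on 3. Samples were grouped by breed from their labels, and slide and dye came from the sample titles. The titles do not say whether the same birds recur across slides. The p-values therefore measure the spread between slides, in the fit below after a dye term, and this spread may be partly technical.

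The values were taken from the deposited table, which has a column per sample. Scanner files were not used here. Image analysis, background treatment, filtering and normalization by the authors are not given in the sources used here. The table has 15769 probes. Of these, 3754 had a value in all 12 columns and 12015 had none in any column, and the rule that left these empty is not given in the sources used here. The deposited values have column medians close to 0. The scale was read from the spacing of low values within each slide, where whole scanner units leave a regular grid. The constant that scales this spacing would be 1 on a natural log scale, 1.443 on a log2 scale and 0.434 on a log10 scale. It was estimated from sets of 3 neighbouring values, as the median of the estimates near the most common one. Slides 1 to 5 gave 1.037 to 1.159. On these slides 708 to 913 such sets were found, of which only those near the most common estimate entered the median. Slide 6 gave 0.997, with only 62 such sets found, since 3705 of its 3754 pairs of channel values were distinct, against 2180 to 2411 on the other slides. It adds little to this reading. The deposited values were therefore treated as natural log intensities relative to the column median, and were divided by 0.693 to give log2 values. If they were log2 values instead, each log2 change printed here would be 0.693 times as large, with the same p-values. The centring constant of each column stays unknown. The lowest value was -0.42 log2 on the first 5 slides and -1.26 on slide 6, which does not settle whether background was subtracted. If it was not, the folds of dim probes are smaller than the folds of their RNA.

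Column medians lay within 0.1 log2 of each other, so the values were used as deposited, by a rule set before the data were examined along with the tests, the alternatives and the rule for naming. The log2 ratio of the 647 over the 555 channel was taken on each slide and fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The fit had a dye term and a breed term, so that the slide acted as a block and the breed coefficient was the log2 value of broiler minus layer. It had 4 residual degrees of freedom, to which the variance model added 1.75. P-values were adjusted by the Benjamini-Hochberg method over the 3720 probes tested, with a threshold of 0.05. The 34 filled probes with control-like IDs were left out of the tests. Of these, 30 have IDs that share their names with 4 plant genes or proteins (Cab, NAC1, PRKase and RUBISCO), and 4 have IDs that refer to chicken genomic DNA. The highest mean of the plant-named probes, 0.11 log2, served to set dim probes apart from the rest. Levels of different probes are not comparable in detail, so this is a filter and not a measure of abundance. It was chosen after the data were seen, and the role of these probes on the array is not given in the sources used here.

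Slide partners were checked for pairing. The deviations of the partners from the means of their breed and dye correlated across probes at 0.807 to 0.871 on the 6 slides. The pairing itself comes from the shared slide in the titles. Groups of probes with a common ID prefix were tested, after the data were seen, with a two-sided exact sign-flip test of the 6 slide medians. The smallest p it allows is 0.03125. Precision is limited by the number of slides.

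The files do not pair probe IDs with gene names, and 0 of the IDs matched the gene table of the chicken assembly GRCg7b. The gene-level fit and the tests of 22 gene lists written in advance, among them erythroid, granulocyte, osteoblast, osteoclast, fat cell and lymphocyte genes, were therefore not run. Their lists hold 0 genes with a value. The rule for naming genes asked, where few pass, for those with the lowest p in each direction and one sign on all slides. It was applied to probes and limited to 2 in each direction. The design had allowed for linear or log2 values, and natural logs were handled as above.

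The fit was tested on simulated data. Normal noise with the probe's own spread and the slide's own share of it was drawn 20 times for all 3720 probes. Known changes of 1.2-, 1.5-, 2- and 3-fold, mixed within each draw, were added to probes above the plant-named level. Large changes ease the adjusted threshold for small ones. The largest measured change above that level was 0.75 log2, so the shares below may be too high for changes like those measured. The noise was scaled by 1.26 above that level and by 1.23 at or below it, so that the simulated SE matched the measured one, a step chosen after the data were seen. The median SE above the level was then 0.0527 in a simulated draw and 0.0523 in the data. With 20 changed probes per draw, 21% of 1.2-fold, 68% of 1.5-fold and 88% of 2-fold changes passed the threshold, with a mean of 0.6 false calls per draw. With 200 changed probes the shares were 46.9%, 85.1% and 95.2%, with a mean of 3.65 false calls. With 200 changed probes at or below the level instead, they were 74.1%, 95.2% and 97.8%, with a mean of 4.45 false calls. The measured median SE was smaller there, 0.0329 against 0.0523. The change was added in full to the listed values, so these shares do not measure the recovery of changes in RNA.

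Alternatives covered within-slide loess, median centring, quantile normalization, leaving out the dye term, dropping or randomizing the slide block, a filter on the dimmest 25% of probes, a trended and robust variance model, other thresholds and leaving out each slide. Slide weights and tests restricted to probes above the plant-named level were added after the data were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.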

Results

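Gene expression in the bone marrow was compared between egg-type and meat-type chickens. The layers were a pedigree line of White Leghorn hens and the broilers a commercial line, with 6 samples of each at 15 weeks of age. Both received a starter diet to 6 weeks, a grower diet to 8 weeks and a developer diet afterwards. The layers ate freely throughout and the broilers were feed-restricted from 6 weeks, so breed and feeding cannot be told apart in this design. Each of 6 slides held a layer and a broiler sample, and all values below are log2 intensities relative to the median of the sample's own channel.

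Values were listed for 23.8% of the 15769 probes on the array, and for 23.4% of the 128 plant-named probes among them. If the plant-named probes have no target in the labelled RNA, a listed value is not in itself a sign of marrow RNA. Whether they have one is not given in the sources used here. The share with values was 42.0% of the 1798 DT40subNB probes, 36.1% of the 1983 Pat probes, 28.6% of the 378 DKFZ426 probes and 18.7% of the 11447 C00041 probes. These are the 4 large groups of probes that share an ID prefix, and the labels do not say what the prefixes stand for. Among the plant-named probes the share ranged from 15.6% for Cab and PRKase to 37.5% for NAC1.

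Of the 3720 chicken probes tested, 1460 (39.2%) had a mean above the highest mean of the plant-named probes, which was 0.11, and 2260 lay at or below it. The highest plant-named value was 1.84 in layer sample 1, 1.87 in broiler sample 1, 1.23 in layer sample 6 and 1.19 in broiler sample 5, so the level does not hold for each probe on each slide.

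The comparison of the breeds asks which transcripts differ in abundance between layer and broiler marrow. In the limma fit with slide as a block, 0 probes were higher and 0 were lower in broilers at an adjusted p under 0.05, and the lowest adjusted p was 0.169. At an unadjusted p under 0.05 there were 240 probes, of which 157 were higher and 83 lower in broilers. Evenly spread p-values would give 186, but this fit need not give evenly spread p-values. Other assignments of breed within slides that keep each breed in each dye on 3 slides gave 10 to 142. There are only 10 of that kind with the real one, too few for a share under 0.05. Of all 31 assignments that can be fitted, 5 gave as many as 240, the real one included. Of the 240, 209 lay above the plant-named level, where 1460 of the 3720 probes tested lay. With slide as a random block limma called 2 probes, with a trended and robust variance model 2, and with weights by slide, chosen after the data were seen, 11. The count at an unadjusted p under 0.05 was 6 without the slide block, 431 with weights by slide and 387 without slide 6. That slide held layer sample 6 and broiler sample 5, whose mean Spearman correlations with samples of their breed were 0.158 and 0.255, against at least 0.631 in the other samples.

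Measured differences were mostly small. Among the 1460 probes above the plant-named level, the median size of the log2 change was 0.06 and the largest was 0.75. The 95% interval of the change lay inside 2-fold in both directions for 1450 of them. These intervals are per probe, without adjustment, and the background treatment of the intensities is not given in the sources used here. A total of 115 probes were higher in broilers on all 6 slides and 79 were lower on all 6, together 194 or 5.22% of the probes tested, where independent signs give 3.125%. Other assignments of breed to the channels of each slide gave 38 to 203 such probes. The balance between directions was 77 higher and 20 lower above the plant-named level, and 144 higher and 148 lower on the 5 slides left without slide 3.

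The probes with the lowest p in each direction and one sign on all slides did not pass the threshold, and their values follow with the limma SE over 6 slides. The files do not pair these IDs with gene names. Probe C0004119_F11 had a mean of 4.29 ± 1.02 (SD, n = 6) in layers and 4.70 ± 0.98 (SD, n = 6) in broilers. Its log2 change was 0.42 ± 0.05 (SE), a 1.33-fold higher level in broilers, with a limma adjusted p of 0.169. The fit has a dye term, so this SE leaves out the gap between the dye orientations. The 6 slide differences of this probe ran from 0.02 to 0.86 with an SD of 0.34. Without the dye term its limma adjusted p was 0.541. The mean difference was 0.12 on the 3 slides where the layer sample carried the 555 dye and 0.71 on the 3 where it carried the 647 dye. Probe DT40subNB_36 had a log2 change of 0.26 ± 0.03 (SE), or 1.19-fold, with a limma adjusted p of 0.169. Its means were 1.32 ± 0.46 (SD, n = 6) in layers and 1.58 ± 0.42 (SD, n = 6) in broilers, and its mean difference was 0.26 with the layer in the 555 dye and 0.25 with the layer in the 647 dye.

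In the other direction, probe C0004129_J15 had a mean of 0.53 ± 0.34 (SD, n = 6) in layers and 0.31 ± 0.30 (SD, n = 6) in broilers. Its log2 change was -0.22 ± 0.04 (SE), with a limma adjusted p of 0.244, and the mean differences by dye were -0.23 and -0.21. In each breed 5 of 6 values lay above the plant-named level, and both values of slide 6, -0.08 and -0.24, lay below it. Probe Pat-21_h5 had a change of -0.69 ± 0.13 (SE), with a limma adjusted p of 0.281. It had means of 0.85 ± 1.04 (SD, n = 6) in layers and 0.15 ± 0.80 (SD, n = 6) in broilers. Only 4 of 6 layer and 2 of 6 broiler values lay above the plant-named level, so no fold is given. Its slide differences ran from -1.06 to -0.02, with means of -0.87 where the layer carried the 555 dye and -0.52 where it carried the 647 dye.

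**Figure D1:**
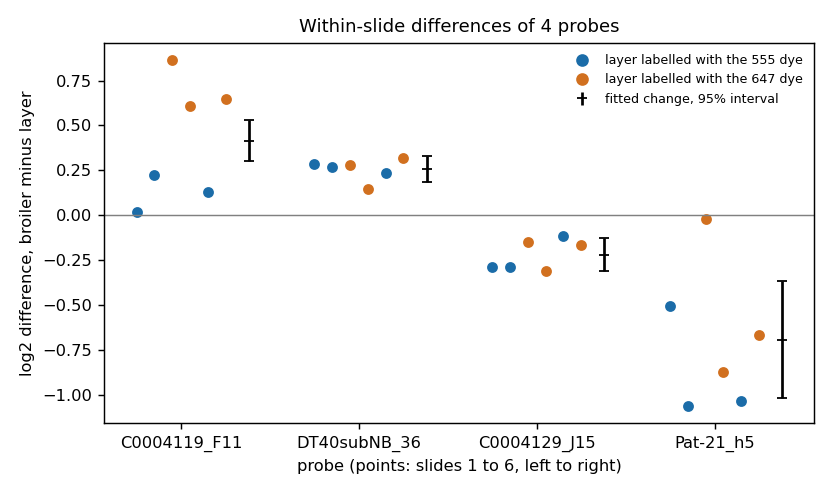
Log2 difference of broiler minus layer (vertical axis) for 4 probes on slides 1 to 6, coloured by the dye of the layer sample, with the fitted change and its 95% interval at the right of each group. All 6 points of C0004119_F11 and DT40subNB_36 lie above 0 and all 6 of C0004129_J15 and Pat-21_h5 below it, and the points of C0004119_F11 separate by dye. The interval comes from the fit with a dye term, so it leaves out that gap.

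Of the 4 prefix groups, Pat had its median on the broiler side on all slides, by a small amount that did not pass the correction. Over the 454 Pat probes above the plant-named level, the mean of the slide medians was 0.03 ± 0.02 (SD, n = 6) and the median was above 0 on 6 of 6 slides. The exact sign-flip p was 0.03125, the smallest that 6 slides can give, and 0.25 after Benjamini-Hochberg adjustment over 8 group tests. The median was above 0 on 5 of 6 slides after median centring or quantile normalization and on 4 of 6 after within-slide loess. At an unadjusted p under 0.05, 58 of these Pat probes were higher in broilers and 13 lower. The DKFZ426 probes above that level had a mean of slide medians of 0.03 ± 0.03 (SD, n = 6; exact p = 0.0938, adjusted 0.25), with 7 higher and 2 lower. The C00041 probes had 0.01 ± 0.01 (SD, n = 6; exact p = 0.188, adjusted 0.375), with 38 higher and 15 lower. The DT40subNB probes had 0.02 ± 0.04 (SD, n = 6; exact p = 0.438, adjusted 0.50), with 41 higher and 35 lower. Without slide 6 the mean was 0.0030 for DT40subNB and 0.0051 for C00041, against 0.0155 and 0.0085 with it. Over all filled probes the mean of the slide medians was -0.0068 for C00041 (above 0 on 2 of 6 slides), 0.010 for DT40subNB (3 of 6), 0.012 for Pat (5 of 6) and 0.0039 for DKFZ426 (4 of 6), with adjusted p from 0.25 to 0.50 in the exact tests.

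The agreement of broiler over layer ratios between slides was compared by dye orientation. Over the 1460 probes above the plant-named level, the mean Pearson correlation was 0.234 for the 6 pairs of slides with the same orientation and -0.0321 for the 9 pairs with opposite orientation. Without slide 6 these means were 0.365 and 0.0627, and without slide 4 they were 0.276 and 0.0250, so the sign of the second rests on those slides. With each of the other slides left out, the first ranged from 0.129 to 0.322 and the second from -0.184 to -0.0114. The difference of 0.266 was the highest among the 10 splits of the slides into 3 and 3 (exact one-sided p = 0.1, the smallest that 10 splits allow), and the next highest was 0.0665. The ranges of the pairs overlapped, and these are correlations across probes, which are not independent replicates. The dye term itself passed the threshold for 0 probes in limma, with a lowest adjusted p of 0.0843.

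**Figure D2:**
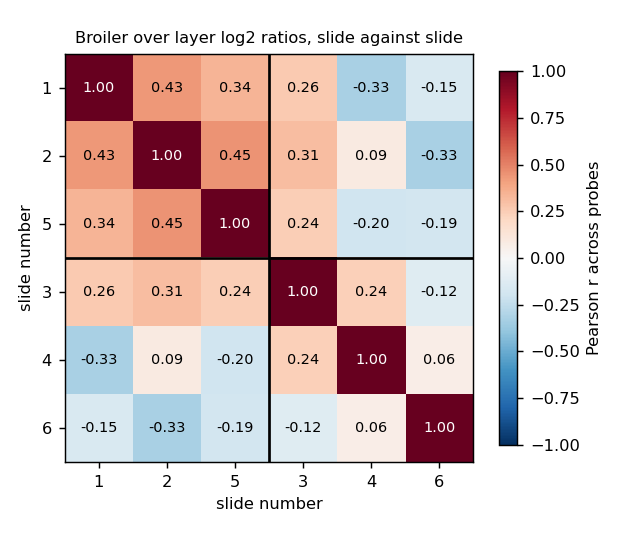
Pearson correlation across probes (colour scale and numbers) of the broiler over layer log2 ratio between each pair of slides; both axes give the slide number, and the black lines part slides 1, 2 and 5 (layer in the 555 dye) from slides 3, 4 and 6 (layer in the 647 dye). Pairs with opposite orientation range from -0.328 to 0.312, and pairs with the same orientation from -0.118 to 0.452.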

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

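All tests that weigh an explanation here were chosen after the data were seen. For plate position and for the correlation of slide 6 with the mean of the other slides, only the limits were set before the test. Values were looked at where the gap of 1 sample to its nearest neighbour took up most of the range of its 6 samples; 23 such groups were examined, and chance picks about 5% of groups.

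Slide 6, which held layer sample 6 and broiler sample 5, stood apart from the other 5 slides in both channels. The mean Spearman correlation with samples of the same breed was 0.158 for layer sample 6 and 0.255 for broiler sample 5, where the next lowest samples had 0.631 and 0.675, and over probes above the plant-named level it was 0.351 and 0.424. The minimum value was -1.23 and -1.26 in these samples, and the lower quartile -0.24 and -0.24. The SD of the within-slide ratio over background probes was 0.347 on slide 6 and at most 0.0993 elsewhere. Of the 3754 pairs of channel values, 3705 were distinct on slide 6 and 2180 to 2411 on the others.

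Breed as the source is argued against, because both channels lay far from the samples of the other slides, the closer of them at a mean correlation of 0.252, while the other 10 samples had 0.752 to 0.838 among themselves. Background that follows plate position is also argued against as the main source, since plate, row and column of the C00041 probes explained a share of 0.0762 of the slide's deviation. A changed order among the listed probes is argued against as the only source, since no order alters the SD of the ratio over all tested probes. This SD was 0.357 here and at most 0.198 elsewhere. The SD does not exclude a changed order on a slide that is also noisier. On slide 6 it was 0.347 over background probes and 0.369 above the plant-named level, against at most 0.0993 and at least 0.199 elsewhere. For an order changed before the probes with values were selected, the test did not decide. The correlation with the mean of the other slides over probes above the plant-named level was 0.382. This lay between the limits set in advance for a changed and an intact order. An order changed at random over all probes would leave no correlation, so the value argues against that. A change of order in part of the probes remains open. Higher scanner or hybridization noise was not tested.

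Broiler sample 2 had a value of 1.68 for probe Pat-21_h5, against 0.14 in the nearest other broiler sample, and layer sample 2 on the same slide had 2.74.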

How the results depend on the processing

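The tests with slide weights, those restricted to probes above the plant-named level and those of the prefix groups were chosen after the result was seen. The count of probes at an adjusted p under 0.05 was 0 with loess, median centring, quantile normalization, no dye term, no slide block, the dim filter, thresholds of 0.01 and 0.1, each slide left out in turn, and only probes above the plant-named level. It was 2 with slide as a random block, 2 with a trended and robust variance model and 11 with slide weights, of which 10 were higher and 1 lower in broilers. Weights set slide 6 to 0.0872. The cause of these changes was not tested. The count at an unadjusted p under 0.05, 240 as reported, was 6 without the slide block, where the partners' shared signal adds to the error, and 431 with slide weights. Leaving out 1 slide gave 161 to 387, the highest without slide 6. The log2 changes of the 4 named probes kept their direction in all 18 alternatives each, which was largely fixed in advance. The probes were picked for one sign on all 6 slides, so leaving out a slide could not reverse them. Several alternatives, such as those without the dye term or without the slide block, leave the estimate unchanged. Adjusted p ranged from 0.0342 to nearly 1 for C0004119_F11 (past 0.05 with slide weights), from 0.0215 to nearly 1 for DT40subNB_36 (past 0.05 with slide weights, and with the trended and robust model) and above 0.05 throughout for the other 2. The unblocked fit changed no other call. The mean of the slide medians above the plant-named level stayed above 0 for each of the 4 prefix groups in the 12 alternatives run on it. Among these, the dim filter and the restriction to probes above that level use the same probes and return the reported values. For Pat the mean ran from 0.019 to 0.033. The exact sign-flip p for Pat was 0.03125 in those settings and 0.0625 to 0.125 in the others. With 5 slides 0.0625 is the smallest it allows. The mean ran from 0.0030 to 0.024 for DT40subNB, from 0.0044 to 0.010 for C00041 and from 0.016 to 0.037 for DKFZ426.

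Gene-level fits, gene list tests and the choice among probes of a gene could not be run without gene names. Adding 50 to linear values had no meaning for logs, and asking for values on all slides removed no probe. Little can be said of the 2260 probes at or below the plant-named level.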

Other observations

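The tests in this part were chosen after the result was seen, except the fit without slide 6, which was planned.

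The breeds were swapped within slides to see how often other assignments give as much. The counts out of 31 and out of 32 below include the real assignment. Of the 31 assignments that can be fitted, all 31 reach the count of 0 past the threshold by its construction (highest other 1234), so this comparison decides nothing. For the 240 probes at an unadjusted p under 0.05, 5 of 31 gave as many, the highest other being 1564, so chance cannot be excluded. For the 11 probes called with slide weights, 6 of 31 gave as many, with 1270 as the highest other, so chance cannot be excluded there either. The highest counts came from the assignment in which the breed term rests on slide 6 alone, where the scatter of that slide gives a high count whatever the breeds, and with slide weights all 5 other assignments with as many probes rest on 1 slide in this way. For the 194 probes with one sign on all slides, 2 of 32 assignments gave as many, the highest other being 203, so chance cannot be excluded. Among the 10 assignments that keep each breed in each dye on 3 slides, the highest others were 142 at an unadjusted p under 0.05, 0 with slide weights and 159 with one sign. Those 10 are too few for a share under 0.05.

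Extra scatter of slide 6 may hide small breed differences. With slide weights 11 probes passed, all above the plant-named level and 9 of them with one sign on all 6 slides. Without slide 6, 0 passed in limma, with a lowest adjusted p of 0.142, while 387 probes had an unadjusted p under 0.05. In the simulated comparison of the breeds over 3720 probes, 20 of them changed, 57% of 1.5-fold changes passed on the 5 slides left and 68% on all 6. For 1.2-fold changes the shares were 14% and 21%. The simulated median SE on the 5 slides was 0.0448, against 0.0465 in the data, and the draws held changes up to 3-fold. These shares may therefore be too high for the data. The tables do not decide whether the scatter hides differences, because the outcomes with weights and without the slide differ.

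Slides of one dye orientation may share a ratio pattern, from dye bias or from breed, but the sharing itself is not established. Their mean covariance was 0.0118 with a jackknife SE of 0.0114, and the pairs of slide 6 with slides 3 and 4 had correlations of -0.118 and 0.0637. Between slides of opposite orientation the covariance of broiler over layer ratios was -0.00344 with a jackknife SE of 0.0116, and for the 647 over 555 ratios it was 0.00344 with the same SE. The second is the first with its sign reversed, so they are the same measurement. Breed predicts a positive value for the first and dye bias for the second, so both together could cancel. The value did not differ from 0 by more than its SE, which for that reason argues against neither. The sign rests on slide 6, whose 3 pairs with slides of opposite orientation had correlations of -0.153, -0.326 and -0.186, and without it the first covariance was 0.00392. The sources cannot be told apart with 6 slides, and birds shared between slides of one orientation stay open as well, since the labels do not number the birds.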
